A study of Rattus norvegicus with 6 samples.

How the data were processed

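The samples were cerebral arteries of Dahl rats, an inbred line whose blood pressure rises on a salty diet, kept from 7 weeks of age on chow with 0.4% NaCl (low salt) or 8% NaCl (high salt). Each sample held RNA pooled from 3 rats, so that 3 arrays per diet stood for 9 rats per diet, per the labels. The labels give the time on the low salt diet as 12 weeks, and the time on the high salt diet as 11 weeks in one field and 12 weeks in another. Arteries were either snap frozen or kept in a preservative, and the labels do not say which sample had which treatment. RNA was amplified in a kit's 2-cycle protocol and hybridised to an Affymetrix rat array, 1 array per pool.

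The deposited table held 1 value per probe set and array, on a log2 scale. The authors' tool was RMA (robust multi-array averaging, which corrects background, equalises arrays and summarises the probes of a set), per the submitters' processing notes; its version is not given in the sources used here. That the base is 2 was read from the range of the deposited log2 values and from the use of RMA, and is not stated in the labels. RMA usually makes the distributions of arrays alike, but medians here ran from 7.96 to 8.17 and the interquartile range from 2.57 to 3.18 across arrays, so that some difference in distribution was left in the values.

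The table had 15923 rows. The 57 control probe sets were left out of the tests, which leaves 15866. Names came from the platform's annotation: 12783 probe sets had 1 gene symbol, 312 had several and 2771 had none here. Of the first kind, 12748 were matched by Entrez identifier to the RefSeq gene table of the assembly GRCr8, and the match changed 0 symbols. No gene was named from a probe set with several symbols. A gene was represented by its probe set with the highest mean over the 6 arrays, which gave 10411 genes, 1868 of them with more than 1 probe set.

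The comparison was fitted with limma (version 3.58.1 in R version 4.3.3), a linear model per probe set with variances moderated across probe sets (lmFit and eBayes), 3 arrays against 3, with no block. Benjamini-Hochberg adjustment ran over all 15866 probe sets, and an adjusted p below 0.05 was called. Differences are high salt minus low salt in log2 units, with the moderated standard error (SE), and SDs are over the 3 arrays of a diet. Since the replicates are pools of separate rats, their spread holds differences between pools and the technical error of each array together. The number of arrays limits the precision.

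Before the data were examined, 20 gene lists and 16 sets of cell type markers were fixed, and tested with camera (limma's competitive set test, preset correlation of 0.01) on 1 probe set per gene, with Benjamini-Hochberg adjustment over all 36. The rule for the genes named in the text was fixed at the same time. It takes the genes past the threshold with no overlap between diets, at most 10 per direction. Where there are none it takes the 5 genes per direction with the lowest unadjusted p among genes above the median level, said to be short of the threshold. It adds up to 4 members of each list with the lowest p, the brightest member and the member of lowest p of each marker set, and a fixed set of matrix, contractile and vasoactive genes. This gave 129 genes, of which the text describes a part. The 7 bone genes besides Col1a1 (Bglap, Alpl, Phex, Dspp, Ibsp, Mepe and Acp5) lie outside this rule and were chosen after the data were examined, with the values of Ibsp and Mepe already seen.

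The steps were tested on simulated data for high salt against low salt, drawn from each probe set's own mean and SD. With 200 of 15866 probe sets changed, limma recovered 39% of those changed by 1 log2 unit and 80% of those changed by 2 log2 units, and called 0 with no change. Unchanged probe sets made up 3 of 81 calls at 1 log2 unit and 17 of 177 calls at 2. For 10411 genes, camera called 6% of random lists of 21 independent genes that were not shifted, and 100% of those shifted by 0.5 log2 units. In the real values the estimated correlation within a list was 0.61 for astrocyte markers and 0.36 for contractile genes. It was -0.03 for the matricellular list. The simulated rates do not carry over to lists whose genes vary together.

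Alternatives fixed before the data were examined were median centring, quantile normalization, a filter at the 40th percentile of mean value, trended and robust variances, array weights, the replicate number as a block, leaving out each array, the mean of a gene's probe sets, adjustment over 1 probe set for each of the 10411 genes, other thresholds, camera with an estimated correlation, and fry (limma's rotation test of a set's own change). Chosen after seeing the data were a covariate for the spiked-in hybridization controls, and the percentile of a list's median among 10000 random lists matched on mean value.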

Results

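Gene expression was measured on 6 arrays of intact cerebral resistance arteries from Dahl rats, branches off the vessel ring at the base of the brain, 3 from rats on low salt chow (0.4% NaCl) and 3 from rats on high salt chow (8% NaCl). Each array held a pool of 3 rats. The study compared the diets to find genes that differ in the arteries of salt-fed, hypertensive rats, over all genes and for groups of genes named in advance. The high salt arrays resembled each other (correlation over probe sets, which are not independent replicates, 0.980 to 0.987), and the low salt arrays less so (0.919 to 0.968). Across diets the correlation ran from 0.926 to 0.988, and the highest of all pairs was low salt replicate 2 with high salt replicate 3. The first principal component held 63.1% of the variance, and on it low salt replicate 1 lay at -65.9, low salt replicate 3 at -15.0, low salt replicate 2 at 28.1 and the high salt arrays from 7.85 to 27.9. No 2 arrays held identical values (0 identical pairs).

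The genes with the lowest p values among well expressed genes included Nes (nestin, an intermediate filament protein), 0.98 ± 0.14 (SE) log2 units higher after high salt, Nol3 (an inhibitor of apoptosis), 0.82 ± 0.14 higher, and Cyp26b1 (a retinoic acid hydroxylase), 0.66 ± 0.12 higher. Ano10 was higher by 0.80 ± 0.15 and the translation factor Eif4g1 by 0.94 ± 0.18. In the other direction, the difference was -1.19 ± 0.27 for Gucy1a1, a subunit of soluble guanylate cyclase, the nitric oxide receptor of smooth muscle. It was -1.04 ± 0.25 for Smim5, -0.36 ± 0.09 for Fads1 (a fatty acid desaturase), -0.92 ± 0.22 for Rgs4 (a regulator of G protein signalling) and -0.67 ± 0.18 for Eif4ebp2. None of these 10 genes overlapped between diets, yet each had an adjusted p of 0.803 (limma, Benjamini-Hochberg). A second probe set gave -0.28 ± 0.13 for Gucy1a1, 0.13 ± 0.10 for Eif4g1 (mean level 5.87) and -0.29 ± 0.24 for Rgs4. Over the 129 genes of the naming rule, 37 had 46 other probe sets, and 14 of these were opposite in sign. By the choice of the brightest, the other probe sets are the dimmer ones of their genes. Several lie below the lower quartile of the arrays (6.53 to 6.65), where a difference says little.

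By limma with Benjamini-Hochberg adjustment 0 genes passed the threshold, and the lowest adjusted p of any probe set was 0.540. At an unadjusted p below 0.05 stood 846 probe sets, 735 higher and 111 lower after high salt, where chance gives 793. The excess of higher probe sets went with a shift of the values that differed by brightness. The median gene was 0.07 log2 units higher, from -0.04 in the dimmest quintile of genes to 0.26 in the brightest. After median centring the split was 384 higher and 433 lower, and the median gene stood at -0.06, so that differences of this size in the text are not distinct from the scaling. Of the 129 genes of the naming rule, 35 moved by more than 1.5 times after median centring, 49 after quantile normalization and 57 after either. Among the 10 genes above these were Cyp26b1 (0.42 after quantile normalization) and Fads1 (-0.59). Arrays of both diets did not overlap for 1770 probe sets, 1147 higher and 623 lower, or 11.2% against the 10% that chance gives.

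The matricellular proteins, secreted proteins of the matrix that act on cells more than they bear load, were the group named in the study's title. Osteopontin (Spp1) was 8.34 ± 0.35 (SD, n = 3) log2 units on low salt and 11.1 ± 1.08 on high salt, a difference of 2.75 ± 0.55 (SE), or 6.74-fold. Periostin (Postn) was 6.63 ± 0.20 on low salt and 9.07 ± 1.57 on high salt, a difference of 2.45 ± 0.76. High salt replicate 2 was the lowest of its group for both, at 9.86 for Spp1. Connective tissue growth factor (Ccn2) differed by 1.11 ± 0.32, Tgfbi by 0.50 ± 0.12 and tenascin C (Tnc) by 0.45 ± 0.16, with Tgfbi at 0.25 after quantile normalization. Sparc (0.31 ± 0.30), Ccn1 (0.01 ± 0.08) and Thbs4 (-0.36 ± 0.20) differed by less than 2 SE, and the sign for Ccn1 turned after median centring. Sparc stood at 0.18 after median centring and 0.08 after quantile normalization, and its second probe set gave 0.01 ± 0.11. Thbs1 was not analysed here.

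**Figure D1:**
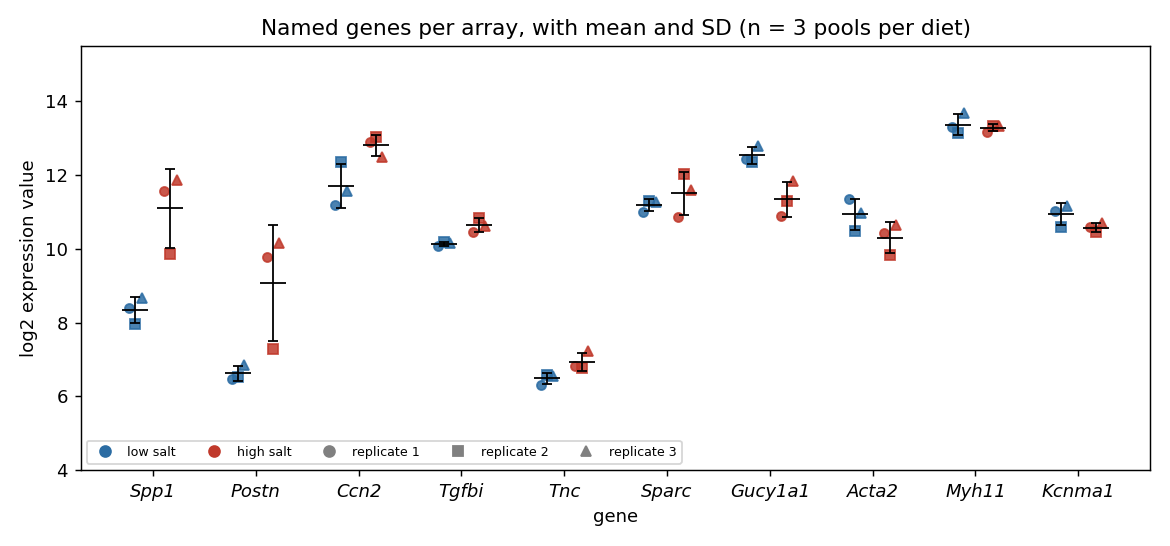
Log2 expression values (vertical axis) of 10 genes (horizontal axis) on each array, low salt in blue and high salt in red, with marker shapes for the replicate, and the mean and SD of 3 pools as black bars. The high salt arrays of Spp1 lie from 9.86 to 11.86, above the low salt arrays, and those of Myh11 overlap with low salt.

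Of the 21 matricellular genes measured, 17 were higher and 4 lower after high salt, with a median difference of 0.21. The median was 0.08 after median centring or quantile normalization, 0.32 without low salt replicate 2 and 0.35 without low salt replicate 3. Over all probe sets 0 members passed the threshold, and 0 did adjusted over the list alone, where the lowest adjusted p (limma, Benjamini-Hochberg) was 0.0533, for Spp1. The list as a whole was called higher by camera (limma, adjusted p = 0.0267, Benjamini-Hochberg over 36 lists). With an estimated correlation camera gave p = 0.0411 before adjustment and 0.599 after it. That was the lowest adjusted p of all 36 lists in that setting, and many lists shared it. At the preset correlation the adjusted p was 0.223 without low salt replicate 2, 0.0505 after quantile normalization, 0.0871 with array weights and 0.0910 with the covariate for spiked-in controls. The study named this group from these samples, so that the direction is not independent evidence. The median lay at the 92.1 percentile of random lists matched on mean value.

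Other matrix genes differed in both directions. Fibronectin (Fn1) differed by 0.95 ± 0.33, the membrane protease Mmp14 by 0.74 ± 0.20 and cathepsin K (Ctsk) by 1.03 ± 0.40. Lysyl oxidase (Lox), which cross-links collagen and elastin, differed by -0.50 ± 0.21, and the collagen Col5a3 by -0.53 ± 0.25. The fibrillar collagens Col1a1 (0.06 ± 0.14) and Col3a1 (0.05 ± 0.24), elastin (Eln, -0.19 ± 0.20), Mmp2 (0.03 ± 0.33) and Timp1 (0.27 ± 0.27) differed by less than 2 SE, and the sign for Col1a1, Col3a1 and Mmp2 turned after median centring and after quantile normalization. Eln stood at -0.32 after median centring and -0.45 after quantile normalization, and Timp1 at 0.14 and 0.07. Of 26 collagen genes 21 were higher, and of 35 genes of elastic fibre, basement membrane and proteoglycans 24 were. Neither list was called by camera (limma, Benjamini-Hochberg adjusted p = 0.222 and 0.639), nor were matrix proteases and inhibitors (0.320) or integrins and focal adhesion genes (0.705).

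Genes of the contractile apparatus of smooth muscle were lower as a group. Of 19 measured, 18 were lower after high salt, with a median of -0.16, and camera called the list (limma, Benjamini-Hochberg adjusted p = 0.000569). With an estimated correlation camera gave p = 0.163 before adjustment and 0.599 after it. At the preset correlation the adjusted p was 0.0775 without low salt replicate 3. The median was -0.05 without low salt replicate 3, -0.25 without replicate 1, -0.34 without replicate 2, -0.29 after median centring, -0.33 after quantile normalization and -0.31 with array weights. Myosin light chain 9 (Myl9) differed by -0.74 ± 0.30, alpha smooth muscle actin (Acta2) by -0.63 ± 0.30, Synpo2 by -0.40 ± 0.22 and the smooth muscle myosin heavy chain (Myh11) by -0.08 ± 0.16. Myh11 stood at -0.22 after median centring and -0.14 after quantile normalization, and its sign turned in at least 1 setting. Of the members of this list 0 passed the threshold, over all probe sets or adjusted over the list alone. Beside this, the mean of the 10 astrocyte markers was 10.3 to 10.6 on the high salt arrays, 8.87 and 8.19 on low salt replicates 1 and 3, and 10.7 on low salt replicate 2, which also had the lowest contractile mean (11.74).

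**Figure D2:**
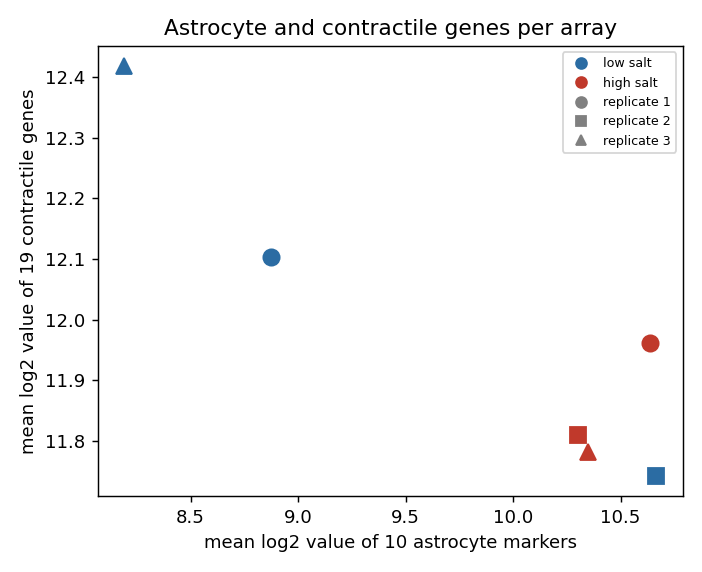
Mean log2 value of 10 astrocyte markers (horizontal axis) and of 19 contractile genes (vertical axis) on each of 6 arrays, low salt in blue and high salt in red, with marker shapes for the replicate. Low salt replicate 2, at 10.7 for astrocyte markers, lies with the high salt arrays.

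Ion channels and calcium handling genes of smooth muscle were also called lower than other genes by camera (limma, Benjamini-Hochberg adjusted p = 0.0230). Of 38 genes 24 were lower after high salt, with a median of -0.05 and a mean of -0.04. The median lay at the 1.14 percentile of random lists matched on mean value. With an estimated correlation camera gave p = 0.172 before adjustment and 0.599 after it. At the preset correlation the adjusted p was 0.0794 without low salt replicate 3 and 0.0505 after quantile normalization. The median was -0.02 without that array, -0.13 without low salt replicate 2, -0.08 without high salt replicate 3, -0.19 after median centring, -0.14 after quantile normalization and -0.10 with array weights. The potassium channels Kcna5 and Kcnma1 differed by -0.62 ± 0.24 and -0.36 ± 0.17, Kcnmb1 by -0.28 ± 0.24, and the stretch-gated channel Piezo1 by 0.53 ± 0.19, and after quantile normalization Kcnma1 stood at -0.59 and Piezo1 at 0.30. The list of renin-angiotensin, endothelin, nitric oxide and other vasoactive genes was called lower (adjusted p = 0.0347, camera in limma with Benjamini-Hochberg adjustment). Of its 44 genes 26 were lower, with a median of -0.04, and with an estimated correlation camera gave p = 0.219 before adjustment and 0.599 after it. This call was lost in 12 of 19 alternatives, among them median centring (0.0793), quantile normalization (0.0956) and the filter at the 40th percentile (0.162), and without low salt replicate 1 (0.178) or 3 (0.0775) or high salt replicate 1 (0.111) or 2 (0.0603). The median was -0.17 after median centring and -0.14 after quantile normalization, turned to 0.05 above the 40th percentile of mean value, and with 1 array left out ran from -0.13 (low salt replicate 2) to -0.000434 (low salt replicate 3). Both soluble guanylate cyclase subunits were on the low side, Gucy1b1 by -0.77 ± 0.26 beside Gucy1a1, while adrenomedullin (Adm) was 0.75 ± 0.21 higher and the natriuretic peptide receptor Npr1 0.45 ± 0.18 higher (0.28 after quantile normalization). The angiotensin receptor Agtr1a (-0.12 ± 0.10) and endothelial nitric oxide synthase (Nos3, 0.05 ± 0.41) differed by less than 2 SE, and the sign for Nos3 turned after both scalings. Agtr1a stood at -0.25 after median centring and -0.10 after quantile normalization. In both lists 0 members passed adjusted over the list alone.

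Genes of the response to oxidative stress were called higher as a list (camera in limma, Benjamini-Hochberg adjusted p = 0.0347), with 27 of 36 higher and a median of 0.23. Genes of interferon response and antigen presentation were called higher too (0.0176), with 19 of 24 higher and a median of 0.35. With an estimated correlation camera gave p = 0.0427 and 0.0834 before adjustment, and 0.599 for both after it. The oxidative stress call was lost in 11 of 19 alternatives, among them without low salt replicate 2 (0.203) or 3 (0.0514) or high salt replicate 3 (0.0907), after quantile normalization (0.0956) and above the 40th percentile (0.0792). The interferon call was lost in 6 of 19, among them above the 40th percentile (0.281), without low salt replicate 2 (0.179) and after quantile normalization (0.0505). Among random lists matched on mean value the oxidative stress median lay at the 89.2 percentile and the interferon median at the 99.27 percentile. After median centring the medians were 0.09 and 0.22, after quantile normalization 0.04 and 0.18, and without low salt replicate 1 0.15 and 0.21, and the interferon median was 0.19 without high salt replicate 3 and 0.21 with array weights. Heme oxygenase (Hmox1) differed by 0.43 ± 0.11, the mitochondrial superoxide dismutase Sod2 by 0.75 ± 0.24, Gstp1 by 0.54 ± 0.17 and Gpx4 by 1.13 ± 0.36. Among interferon-induced genes Rsad2 differed by 1.95 ± 0.58 and Mx2 by 0.63 ± 0.17, and the class II antigen genes RT1-Db1 by 0.63 ± 0.15 and RT1-Bb by 0.52 ± 0.15. After quantile normalization Hmox1 stood at 0.28, Gstp1 at 0.34, RT1-Db1 at 0.38 and RT1-Bb at 0.29. Second probe sets, dimmer at mean levels of 5.36, 7.89 and 6.14, gave -0.15 ± 0.10 for Mx2, 0.14 ± 0.10 for RT1-Db1 and 0.000838 ± 0.11 for RT1-Bb. In both lists 0 members passed, over all probe sets or adjusted over the list alone.

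The remaining gene lists were not called by camera (limma, Benjamini-Hochberg). Adjusted p was 0.0523 for complement, with C1r 0.71 ± 0.20 and C1qa 1.19 ± 0.34 higher, 0.0761 for unfolded protein response and heat shock, 0.0900 for TGF-beta and BMP signalling, and 0.111 for glycolysis and hypoxia. It was 0.393 for immediate early genes, where Junb differed by 1.04 ± 0.26 and Klf4 by 0.51 ± 0.15 (0.29 after quantile normalization), 0.394 for the circadian clock, 0.414 for oxidative phosphorylation and 0.680 for cholesterol and fatty acid metabolism. Proliferation genes (0.501) and cytokines and adhesion molecules (0.838) had medians of 0.01 and 0.03 while camera put them lower than other genes. In all of these 0 members passed adjusted over the list alone.

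**Figure D3:**
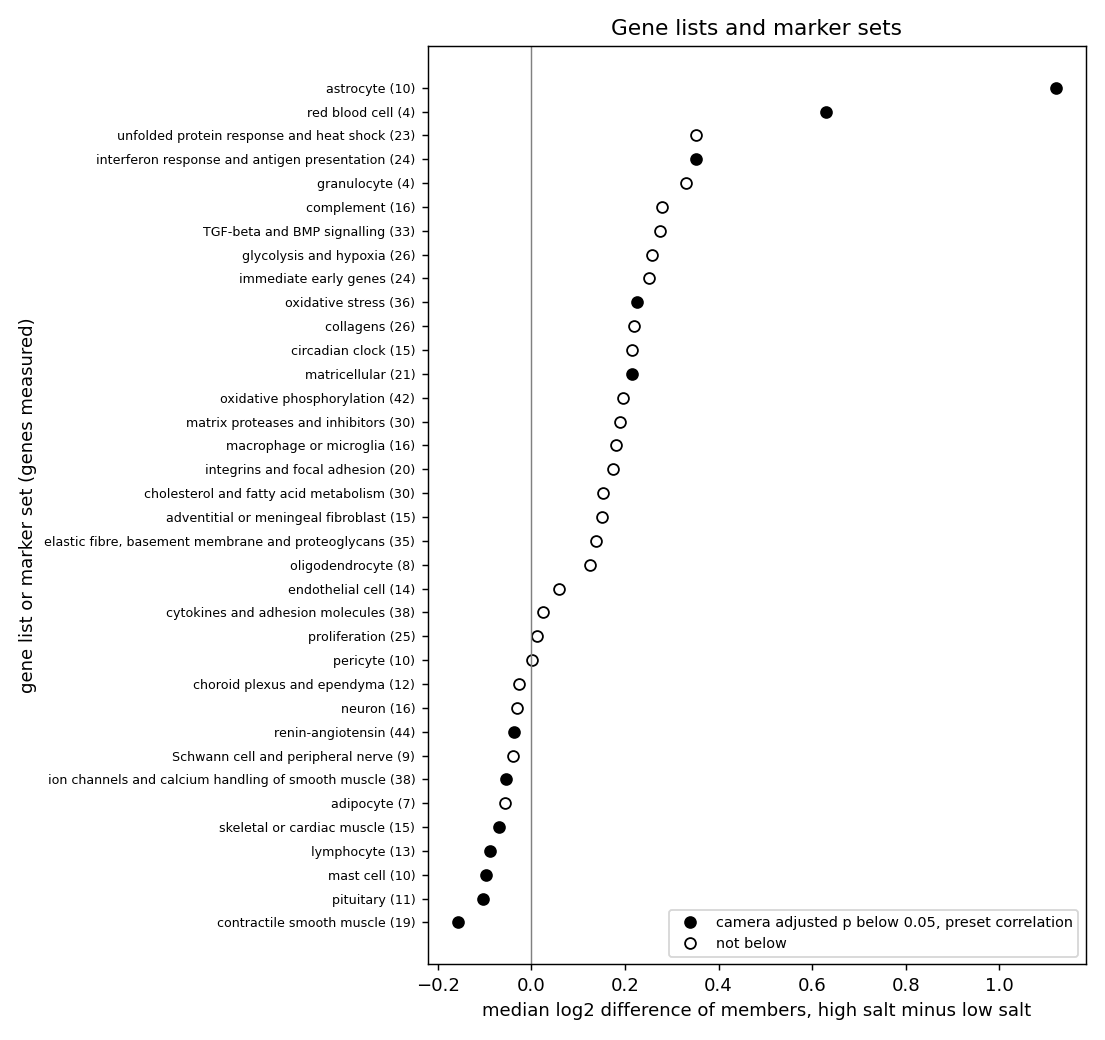
Median log2 difference, high salt minus low salt, of the members of each of 36 gene lists and marker sets (horizontal axis), with the number of genes measured after each name. Filled points have a camera adjusted p below 0.05 at the preset correlation, and the astrocyte set stands farthest to the right at 1.12.

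Markers of cells other than smooth muscle were compared in the same way, with camera in limma and Benjamini-Hochberg adjustment. Astrocyte markers were called higher (adjusted p = 0.0230, 9 of 10 higher, median 1.12, or 0.52 without low salt replicate 3). Mlc1 differed by 1.92 ± 0.94 and Gja1 by 0.71 ± 0.49. The other, dimmer probe sets of Gja1 (mean level 6.05 and 6.81) gave -0.14 ± 0.09 and -0.04 ± 0.25. Red blood cell markers were called higher (0.0338, 4 of 4), and Hbb, at 0.94 ± 0.24, was the 1 gene of that set that passed adjusted over the list alone (0.0361). Called lower were lymphocyte (0.0267), mast cell (0.0176), pituitary (0.0267) and skeletal or cardiac muscle markers (0.0183), sets with a median level from 6.13 to 6.86 and medians from -0.10 to -0.07. Against random lists matched on mean value these 4 medians lay at the 8.53, 6.09, 7.21 and 7.5 percentiles, inside the central 95%. After median centring these 4 medians were -0.22, -0.23, -0.23 and -0.20, and without low salt replicate 1 they were -0.05, -0.05, -0.00822 and 0.01. Without high salt replicate 1 the lymphocyte median was -0.03 and the mast cell median -0.05, and without low salt replicate 2 the muscle median was -0.17. The pituitary median was -0.17 after quantile normalization and -0.06 with array weights, and the muscle median was -0.58 over the 5 genes above the 40th percentile of mean value. With an estimated correlation camera gave p from 0.0578 (red blood cell) to 0.305 (pituitary) before adjustment, and 0.599 for each of these 6 sets after it. Leaving out low salt replicate 3 ended the astrocyte (0.210) and red blood cell calls (0.0742). Without low salt replicate 1 the mast cell (0.0603), pituitary (0.533) and muscle calls (0.301) were lost, without low salt replicate 2 the lymphocyte (0.172) and red blood cell calls (0.278), and without high salt replicate 1 the same 2 sets (0.193 and 0.108). Above the 40th percentile the lymphocyte (0.511) and red blood cell calls (0.0792) were lost, with array weights the pituitary call (0.115) and with the spiked-in control covariate the astrocyte call (0.0818). Quantile normalization ended the lymphocyte (0.248), mast cell (0.158), red blood cell (0.0505), pituitary (0.180) and muscle calls (0.260). Adjusted p was 0.978 for endothelial cells and 0.407 for pericytes, which camera put lower at medians of 0.06 and 0.00202. It was 0.572 for adventitial or meningeal fibroblasts, where Penk differed by 1.49 ± 0.41 and Ptgds by 0.26 ± 0.16 (0.13 after median centring). It was 0.445 for macrophages or microglia, 0.394 for granulocytes, 0.172 for neurons, 0.907 for oligodendrocytes, 0.307 for Schwann cells, 0.290 for choroid plexus and ependyma and 0.320 for adipocytes.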

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

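Under every alternative run, 0 genes passed an adjusted p of 0.05 by limma with Benjamini-Hochberg adjustment, as in the values reported, and 0 passed 0.10 except without low salt replicate 2, where 81 did. Probe sets at an unadjusted p below 0.05 numbered 735 higher and 111 lower as reported. They numbered 384 and 433 after median centring, 365 and 403 after quantile normalization, 1151 and 288 with array weights, and 1782 and 322 with the spiked-in control covariate, which was chosen after seeing the data. Fewer probe sets were tested above the 40th percentile, where 542 were higher and 55 lower. The same holds with adjustment over 1 probe set for each of the 10411 genes, where 560 were higher and 60 lower. Leaving out 1 array gave 312 to 2026 higher and 54 to 696 lower, the highest of both without low salt replicate 2. Groups without overlap numbered 1164 among the probe sets above the 40th percentile and 1770 among all. Since the filter leaves fewer probe sets, the lower count is not a loss of such probe sets.

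The matricellular list had a camera adjusted p (limma, Benjamini-Hochberg) of 0.0505 after quantile normalization, 0.0871 with array weights, 0.0910 with the covariate, 0.599 with an estimated correlation and 0.0747 by directional fry, and 0.00939 by mixed fry, which asks only for change in either direction, against 0.0267 as reported, and 0.00891 to 0.223 with 1 array left out. Before adjustment, camera with an estimated correlation gave this list p = 0.0411. Its percentile among matched random lists, a description chosen after seeing the data, was 92.1. Of the other 35 lists, 11 were called as reported and 13 after median centring. That scaling added complement, unfolded protein response and TGF-beta and BMP signalling, and lost the vasoactive list. After quantile normalization 2 were called (contractile smooth muscle and astrocyte), 5 above the 40th percentile, and 0 with an estimated correlation, by directional fry or by mixed fry. Leaving out 1 array gave 6 to 12. Of the 35 lists, called or not, 7 lay outside the central 95% of matched random lists. Among these were granulocytes (99.78 percentile) and TGF-beta and BMP signalling (97.54), which camera did not call as reported. Apart from tests on fewer samples or probe sets, the cause was not tested. With the replicate number as a block, 621 probe sets were higher and 95 lower, 0 genes passed, the matricellular list stood at 0.0215 and 13 other lists were called. Deviations of arrays with the same number correlated at 0.04, -0.27 and 0.04, so that the numbers do not pair the arrays. Of 129 named genes, 12 had another sign in at least 1 setting. A 1.5-fold minimum was not applied to lists.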

Other observations

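Among the tests in this part, only the splits for the matricellular list were set out before their results were seen. The others were chosen after it.

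Among 8 genes of bone, Ibsp (bone sialoprotein) differed by 1.45 ± 0.64 (SE) log2 units and Mepe (an extracellular phosphoglycoprotein) by 1.80 ± 0.70, with high salt replicate 2 inside the low salt range for both. Bglap, Phex, Dspp and Acp5 differed by -0.07, -0.11, -0.05 and -0.05, Alpl by 0.13 and Col1a1 by 0.06. By limma with Benjamini-Hochberg adjustment 0 of the 8 passed the threshold.

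The higher values of Spp1 and Postn were set against tissue carried along in the pools. Whether bone fragments came along cannot be told apart: the median of the 8 bone genes was 0.00434, but with an SE over genes of 0.27 and members that went both ways, among them Ibsp and Mepe, whose values were known when the list was chosen. Whether more macrophages, which also make Spp1, were in the high salt pools cannot be told apart either. The median of 16 macrophage markers was 0.18 with an SE over markers of 0.11. It lay at the 51.54 percentile of random lists matched on mean value. An effect of the diet on the artery wall stays open and was not tested apart from the group comparison.

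On 6 arrays the astrocyte mean was higher, and the contractile mean lower, on the high salt arrays and low salt replicate 2 than on low salt replicates 1 and 3. Differences in how much adhering glial tissue each pool held, whatever the diet, may account for both: the astrocyte mean ranged over 2.47 log2 units within low salt, against 1.18 between diets, and 1 of 3 low salt arrays reached the high salt arrays. Marker medians of other wall cells were 0.06 (endothelial cells), 0.00202 (pericytes) and 0.15 (adventitial or meningeal fibroblasts). Differences of this size are not distinct from the scaling, so they do not decide whether glia diluted the whole wall. Whether neurons came along cannot be told apart, since only 3 neuron markers were above the median gene level (median difference 0.55, SE 0.30). Over all 16 neuron markers measured, at a median level of 7.22, the median difference was -0.03, with 8 higher and 8 lower. An effect of the diet stays open: the astrocyte mean minus the contractile mean differed by 1.42, with an exact two-sided permutation p of 0.4, where 3 against 3 cannot go below 0.1.

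More probe sets were higher than lower at an unadjusted p below 0.05, 86.9% of them. Low salt replicate 1 had the narrowest distribution and the strongest spiked-in controls (9.71 log2 units), but without it 84.0% were higher, which argues against that array as the whole cause. The 3' minus 5' difference of the Gapdh control probe sets, a measure of RNA integrity, was 3.30 on that array and 1.94 to 2.69 on the others. For beta-actin it was 3.20 on that array and 3.16 to 3.89 on the others. Differences went with brightness: the median gene differed by -0.04 in the dimmest quintile and by 0.26 in the brightest. After quantile normalization 47.5% of such probe sets were higher, and after median centring 47.0%. Median centring takes out only 1 constant per array, so that the excess rested on an offset between arrays. Whether this offset and its dependence on brightness came from the processing or from the diet cannot be told apart by either scaling. A diet effect on many genes one way stays open.

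Over the 6 arrays the mean of 14 spiked-in control probe sets and the first principal component had a Pearson r of -0.80 (exact permutation p = 0.0403, Benjamini-Hochberg adjusted over 2 relations 0.0403) and a Spearman rho of -0.83 (exact permutation p = 0.0583, adjusted 0.0583). Without the 2 arrays farthest from the median control value r was -0.71. For the astrocyte and contractile means r was -0.92 (exact permutation p = 0.0181, adjusted 0.0361) and rho -0.83 (exact permutation p = 0.0583, adjusted 0.0583). Without low salt replicates 1 and 3, the arrays farthest from the median astrocyte mean, r was 0.26, so that this relation rests on those 2 arrays.

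The 6 arrays can be split in 10 ways into 3 against 3, too few for a share under 0.05. All 10 splits gave 0 genes past the threshold, as the real one did. For probe sets at an unadjusted p below 0.05 the real split gave 846, and 3 of the 10 gave as many, the highest other being 2284, for low salt replicates 1 and 3 with high salt replicate 2 against the rest. For the matricellular list the real split gave a camera p of 0.00668, the lowest of the 10 (1 as low), and the lowest other was 0.0147 (limma). The study named this group from these same samples, which could favour the real split, so that its rank is not independent evidence.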
